A study of Mus musculus with 8 samples.

How the data were processed

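RNA of mouse brain was measured on 8 one-colour oligonucleotide arrays, 1 array per mouse: 2 mice at day 0 that had drunk water, 3 given trehalose for 1 day and 3 given it for 10 days. Per the labels' protocols, total RNA was extracted with Trizol, amplified with amino allyl labelling, coupled to Cy5 and hybridised by the array manufacturer's protocol. The deposited scanner files hold, per the file headers, an intensity for each spot (the median of its pixels in 1 channel) that was read at 3 gains joined by least-squares lines, a local background intensity, and a flag for each gain. Software, scan date and slide were not given in the sources used here, so none of these could be tested as a batch. The replicate number and the number that opens each description were tried as a block and as a covariate. A second deposited table of the authors holds a processed intensity per probe on a linear scale; set against the scanner values, each of its columns was a straight line through the spot medians, close to the spot minus the mean of the blank spots, scaled to a median of 25. The authors' table had no value for 1502 to 2763 probes per array.

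Each array held 27456 spots, of which 23474 carried 23473 probes and 2736 were blank. The platform annotation paired 20690 probes with 1 gene symbol each; the other 2783 had no listed gene and were reported only by count, and none was listed with several genes. Symbols were updated through the gene identifiers of the reference table where they matched.

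Log2 intensities were computed from the spot medians with limma 3.58.1 in R 4.3.3. The background was corrected by normexp with an offset of 50, fitted on all spots. The local background column was not subtracted because it followed the spots themselves, with a correlation of log intensities between 0.943 and 0.985 per array across spots. The offset compresses changes of dim probes. Spots with a failed flag at any gain were set to missing, which removed 10 probe spots. Arrays were then quantile normalized, and spots of the same probe were averaged. A probe was tested if it lay above the mean plus 2 SD of the blank spots on at least 2 arrays, which left 21583 probes, 19122 of them with a symbol, for 17863 symbols. Of these symbols, 1179 had more than 1 probe. Probes of a gene were kept apart, and at 1 day against control 572 of the 1179 genes had probes of opposite sign, though only 1 of them at an unadjusted p under 0.05 for all its probes. On these arrays 86.3% to 92.1% of the probes lay above the limit, and the median spot was 2.45 to 2.87 times the blank mean. The number of arrays limits the precision: the median 95% interval of a log2 change reached 0.130 to each side in the comparisons with control and 0.117 between the 2 times.

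All 8 arrays entered 1 limma fit with the 3 groups, which left 5 residual degrees of freedom. Each comparison was a contrast of group means, moderated by eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. A set of 42 gene lists of pathways, cell types and brain regions was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated for each list, and fry, were run beside it. The groups, tests, gene lists, the other settings to be tried and the rule for named genes were set before the data were examined.

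The rule named, for each comparison, the 12 largest rises and falls past the threshold. Places left empty were filled with the lowest unadjusted p among probes with a log2 change of at least 0.58 and no overlap between the groups, which are stated as not past the threshold. It also named up to 2 members of each list with the lowest p where none passed, and always a set of trehalase, glucose transporter, autophagy, lysosome and chaperone genes. Hspa1b, one of that set, was not among the listed genes tested and has no value here. Clone names, numbered gene models and probes without a listed gene were counted and not named.

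The procedure was tested on simulated data drawn from the means and moderated SDs of the 21583 probes, with 200 probes changed in each of 10 draws per comparison. The changes were added to log2 intensities that already held the offset, so for dim probes they stand for larger changes. At 1 day against control it recovered 64.4% of the 1.25-fold, 93.8% of the 1.5-fold and 99.6% of the 2-fold changes. At 10 days against control the shares were 59.4%, 94.2% and 99.4%, and between the times 68.6%, 96.8% and 99.6%. For trehalose at either time against control they were 72.2%, 94.6% and 99.2%. A list shifted by 0.1 on the log2 scale was called in 10 of 10 draws of each comparison. At 1 day against control 6.19% of the calls were false, and in the other comparisons 4.38% to 4.95%. The simulation drew probes independently, so it says nothing about lists whose genes vary together. Each draw held 200 changed probes, which eases the adjusted threshold, so the shares do not hold where few probes change. They therefore do not exclude single changes of these sizes in the data.

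The alternatives were other background corrections, normalizations and filters, the authors' table, other variance models and array weights, the compared groups alone, a block for the replicate number, and each array left out in turn. Added after seeing the data were the local background column, flagged spots kept, the sample number as a covariate, 1 probe per gene for the lists, and several gene-level choices applied to the lists.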

Results

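The series asked what drinking trehalose, a disaccharide of glucose, does to gene expression in the mouse brain. Male C57Bl/6J mice drank water, or trehalose for 1 or 10 days, and were fasted, anesthetized and perfused before the brain was taken. The labels place the tissue in the cerebral cortex, while the design text speaks of the frozen left hemisphere, so the exact dissection is open. Mice were caged in groups of 3, and the labels do not say which mice shared a cage. The water group held 2 mice and each trehalose group 3. Water mice were sampled at day 0 only, with none at 1 or 10 days. In all comparisons an effect of trehalose therefore cannot be told apart from one of the time of sampling.

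The 8 profiles were very similar. Pearson correlations of log2 intensity across the 21583 tested probes lay between 0.994 and 0.998, with a median of 0.9962 within groups and 0.9961 between them. Genes are not independent replicates, so these correlations only describe the arrays. The first principal component held 25.3% of the variance and did not separate the groups, each of which held values on both sides of 0. It followed the number that opens each sample's description, which runs from 1 to 8 and alternates between the groups, with Pearson's r = 0.932 (exact permutation p = 0.00144) and Spearman's rho = 0.952 (exact permutation p = 0.00114) over 8 samples. Without samples 1 and 8, r was 0.944. The labels do not say what this number means.

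**Figure D1:**
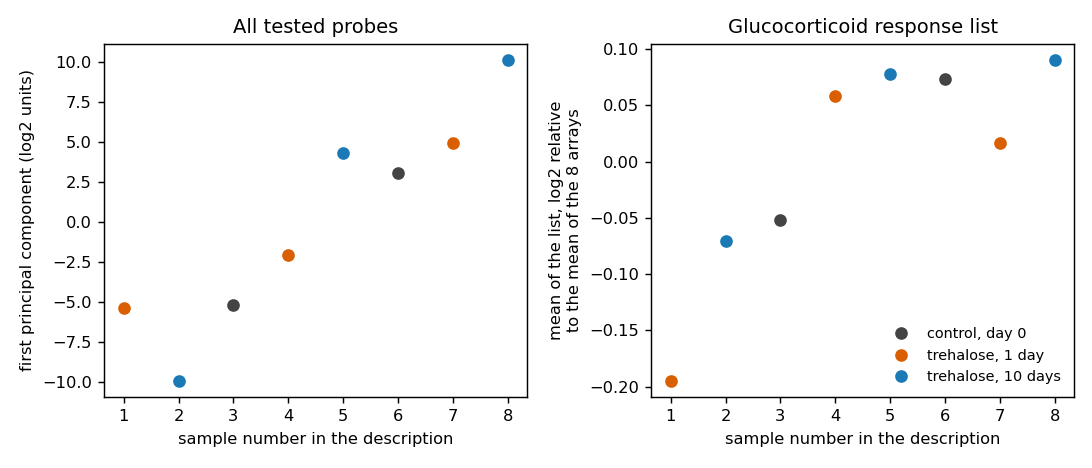
The first principal component of all tested probes (left, log2 units) and the mean of the glucocorticoid response list relative to the mean of the 8 arrays (right, log2) are plotted against the number in the sample description, 1 point per array, coloured by group. The component rises with the number (r = 0.932) while the 3 groups are interleaved along it.

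The question of the first comparison was what 1 day of trehalose changed. Among named genes whose groups did not overlap, the largest differences from control were in Xlr3c and Xlr3a, 2 members of an X-linked multicopy family. Log2 intensity of Xlr3c was 6.56 ± 0.23 in control (SD, n = 2) and 7.82 ± 0.08 after 1 day (SD, n = 3), a 2.40-fold difference, and that of Xlr3a was 6.33 ± 0.29 against 7.26 ± 0.14, or 1.90-fold. Avp, which encodes the hypothalamic hormone vasopressin, measured 9.19 ± 0.13 in control and 9.94 ± 0.42 after 1 day. Lower values were measured for Olfr1412, an olfactory receptor gene, with a log2 change of -0.65 (SE 0.17), and Glipr1l2, with -0.59 (SE 0.21). None of these 5 genes passed the test across all probes. Near-identical copies within the Xlr3 family make it uncertain which copy each probe reads.

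By limma, 0 of 21583 probes passed an adjusted p of 0.05 at 1 day, and the smallest adjusted p was 1.0. At an unadjusted p under 0.05 there were 787 probes, 437 higher and 350 lower, where chance alone gives about 1079. The groups did not overlap for 18.2% of the probes, against 20% by chance for 2 arrays against 3. For 98.6% of the probes the 95% interval of the change stayed within 0.58 on the log2 scale. Without control replicate 1 the log2 changes of Sult4a1 and Ifitm3, named after their values were seen, were 1.98 and 1.31. With all arrays they were 1.01 and 0.60. The larger changes rest on control replicate 2 alone. Sult4a1 measured 7.74 there, against 9.69 in control replicate 1 and 9.68 to 9.78 after 1 day.

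**Figure D2:**
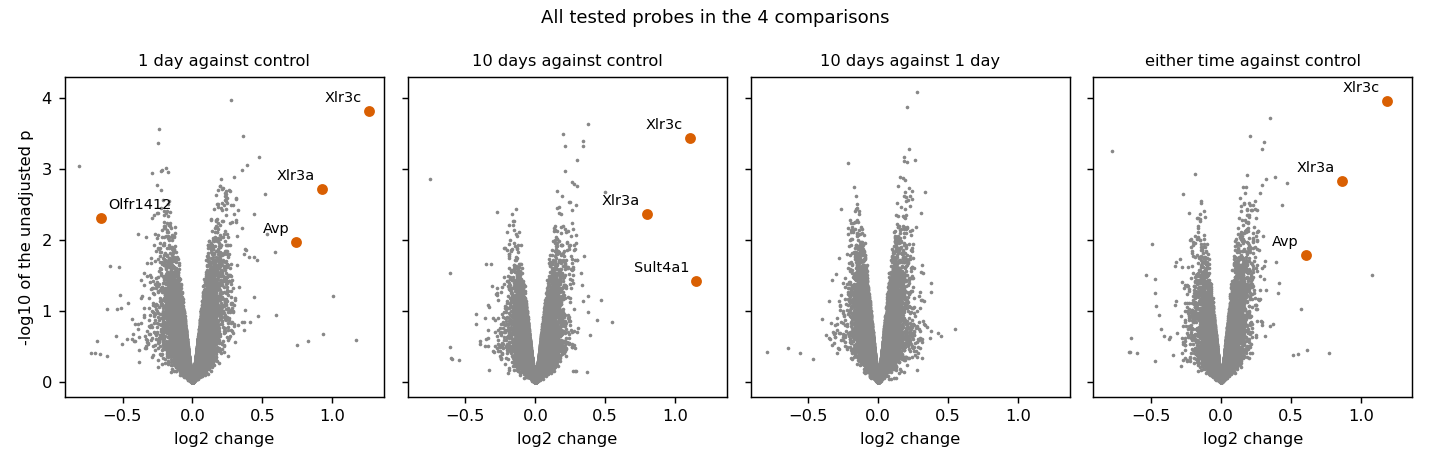
Each point is 1 of the 21583 tested probes, with its log2 change on the horizontal axis and -log10 of its unadjusted limma p on the vertical axis, in 1 panel per comparison; orange points are some of the named genes, with their symbols. In no panel did a probe pass an adjusted p of 0.05, and Xlr3c and Xlr3a stand to the right in the 3 comparisons with control.

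Markers of 2 brain regions, thalamus and striatum, had the lowest p of the 42 lists after 1 day by camera at the preset correlation. Thalamus markers rose as a set by camera (adjusted p = 5.13e-05), with 15 of 19 probes higher and a median log2 change of 0.17. The call was lost with an estimated correlation (adjusted p = 0.601). The median of the list was 0.074 without trehalose 1 day replicate 2 and 0.045 without control replicate 1. Slc17a6, the vesicular glutamate transporter of thalamic neurons, measured 8.96 ± 0.08 in control and 9.48 ± 0.22 after 1 day, and it passed with Amotl1 when adjusted over the list alone, 2 of 19 probes against 0 over all probes. Striatum markers fell as a set (adjusted p = 3.56e-04), with all 16 probes lower and a median of -0.29. This call was lost with an estimated correlation (adjusted p = 0.665) and without trehalose 1 day replicate 2 (adjusted p = 0.878 by camera). The median of the striatum list was -0.047 without trehalose 1 day replicate 2 and -0.16 without control replicate 1. No striatum probe passed when adjusted over the list alone. Ppp1r1b, the dopamine-regulated phosphatase inhibitor of striatal projection neurons, had a log2 change of -0.61 (SE 0.32), and the sodium channel subunit gene Scn4b one of -0.15 (SE 0.06).

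Markers of choroid plexus and ependyma were higher as a set after 1 day (adjusted p = 0.0235, and adjusted p = 0.731 with an estimated correlation), with 13 of 15 probes higher. Foxj1, a regulator of ciliated cells, had a change of 0.16 (SE 0.06) and Clic6 one of 0.12 (SE 0.06). Microglia and macrophage markers were lower (adjusted p = 0.0428, and adjusted p = 0.665 with an estimated correlation), with 13 of 19 probes below control and C1qc, a complement gene, at -0.22 (SE 0.06). Excitatory neuron markers were lower too (adjusted p = 0.0428, and adjusted p = 0.601 with an estimated correlation), with 15 of 19 probes lower. Their member with the lowest p was Slc17a6, which was higher and the only one to pass adjusted over the list alone. Slc17a6 belongs to both the thalamus and the excitatory neuron list.

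At 1 day fry called 0 lists, with a smallest adjusted p of 0.199. Leaving out trehalose 1 day replicate 2 ended the calls of striatum (adjusted p = 0.878), choroid plexus (0.895, with the direction turned), microglia (0.760) and excitatory neurons (0.0946). Leaving out control replicate 1 ended all 5, with adjusted p = 0.210 for thalamus, 0.532 for striatum, 0.844 for choroid plexus, 0.265 for microglia and 0.532 for excitatory neurons. The microglia call also ended without control replicate 2 (adjusted p = 0.0671), and that of excitatory neurons without trehalose 1 day replicate 1 (0.0657) or 3 (0.0782). Other settings ended calls too: blank subtraction those of choroid plexus (adjusted p = 0.0547), microglia (0.0547) and excitatory neurons (0.0793), median scaling those of microglia (0.0521) and excitatory neurons (0.0521), and 1 probe per gene (0.115) and the authors' table (0.0876) that of excitatory neurons. With the local background column, added after seeing the data, 0 lists were called and the changes of Slc17a6 and Amotl1 turned to -0.58 and -0.23.

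**Figure D3:**
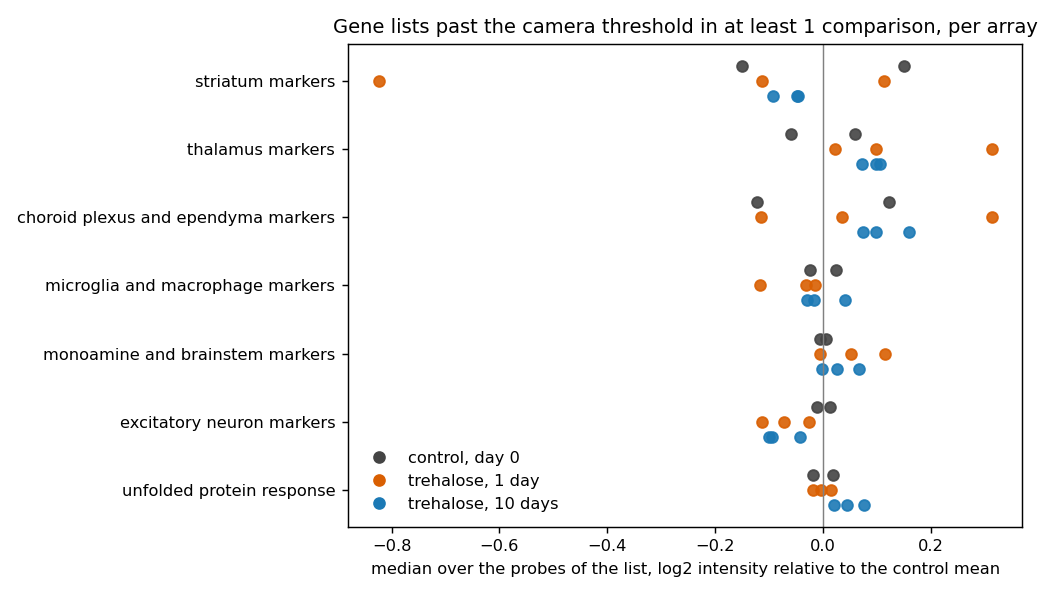
For each of the 7 lists called in at least 1 comparison, points give the median log2 intensity of its probes relative to the control mean, 1 point per array, coloured by group. One 1-day array lies at -0.82 for striatum markers, while the other arrays lie between -0.15 and 0.15, and the same array is highest for thalamus markers at 0.31.

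Genes tied to how trehalose is digested and taken up were measured after 1 day as well. Treh, which encodes the enzyme that splits trehalose, had a log2 change of 0.01 (95% interval -0.09 to 0.11), and Slc2a8, a glucose transporter reported to carry trehalose, one of 0.00 (-0.09 to 0.09). The autophagy list was not called (adjusted p = 0.607), with 19 of 40 probes higher and 21 lower. Among its genes, Nbr1, an autophagy receptor, had a change of -0.13 (SE 0.05), which turned to 0.12 with the local background column, and Map1lc3a one of -0.19 (SE 0.09). The lysosome list was not called either (adjusted p = 0.983), and its median (0.0074) and mean (-0.0036) differed in sign. Its member Gaa, the lysosomal enzyme that breaks down glycogen, had a change of 0.27 (SE 0.06). Tfeb, the transcription factor that drives lysosomal genes, had a change of -0.02 (95% interval -0.15 to 0.11).

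In the remaining lists, single members passed only when adjusted over the list alone. Scd2, a fatty acid desaturase, did so in the fatty acid synthesis list with a change of 0.20 (SE 0.04), and Pdia6, a protein disulfide isomerase, in the unfolded protein response list with -0.23 (SE 0.05). Each was 1 member of its list, and 0 passed over all probes. With the local background column Scd2 stood at -0.42.

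The second comparison asked what 10 days of trehalose changed. Xlr3c was again higher than control, at 7.66 ± 0.35 (SD, n = 3) against 6.56 ± 0.23 (SD, n = 2), or 2.16-fold, and Xlr3a was 1.74-fold higher at 7.13 ± 0.34. Sult4a1, a brain sulfotransferase, had a log2 change of 1.15 (SE 0.46), which came with an SD of 1.38 between the 2 controls. Olfr1441, an olfactory receptor gene, had a change of -0.61 (SE 0.23). Chordc1, a co-chaperone of Hsp90, measured 7.65 ± 0.03 in control, 7.77 ± 0.09 after 1 day and 7.95 ± 0.04 after 10 days. None of these 5 genes passed the test across all probes.

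At 10 days limma called 0 of 21583 probes, with a smallest adjusted p of 1.0. At an unadjusted p under 0.05 there were 432 probes, 265 higher and 167 lower, against 1079 by chance, and 13.4% of the probes had groups that did not overlap, against 20% by chance. Without control replicate 1, so against control replicate 2 alone, the log2 changes of Sult4a1 and Ifitm3 were 2.13 and 1.26. Il1rl2, an interleukin receptor gene also named after its values were seen, was the only call with trend and robust variances (adjusted p = 0.0188) and after subtraction of the blank mean (adjusted p = 0.00799). Its log2 change was 0.20 in the former and 1.31 in the latter. The latter setting put low values at a common floor and gave the same change, 1.31, against 1 day. Equal changes arise where control and 1-day values sit at that floor, so this probe may lie at background.

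Of the chaperone lists, 1 was called after 10 days. The unfolded protein response list rose as a set by camera (adjusted p = 0.0190), with 18 of 25 probes higher and a median of 0.05. The call was lost with an estimated correlation (adjusted p = 0.473). Hspa5, the main chaperone of the endoplasmic reticulum, measured 11.16 ± 0.02 in control and 11.42 ± 0.08 after 10 days, and Derl3, of the degradation machinery there, had a change of 0.14 (SE 0.05). No member passed when adjusted over the list alone. The list of cytosolic heat shock proteins was not called (adjusted p = 0.0821), though Chordc1, with a change of 0.30 (SE 0.06), passed when adjusted over the list alone, 1 of 27 probes against 0 over all probes. Hspa4 of the same list had a change of 0.26 (SE 0.09).

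Thalamus markers rose as a set at 10 days as well (adjusted p = 2.18e-05, and adjusted p = 0.756 with an estimated correlation), with 18 of 19 probes higher, and Slc17a6 had a change of 0.35 (SE 0.12). All 15 choroid plexus and ependyma probes were higher (adjusted p = 0.0112, and adjusted p = 0.782 with an estimated correlation), with Clic6 at 0.14 (SE 0.06). Excitatory neuron markers were lower (adjusted p = 0.0352, and adjusted p = 0.473 with an estimated correlation), with 15 of 19 probes lower and Nrgn, a postsynaptic calmodulin-binding protein, at -0.19 (SE 0.06), which turned to 0.18 with the local background column. None of these 3 lists held a probe that passed when adjusted over the list alone.

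At 10 days fry called 0 lists, with a smallest adjusted p of 0.793. Without control replicate 1 no list was called, with adjusted p = 0.377 for thalamus, 0.757 for choroid plexus, 0.377 for the unfolded protein response and 0.538 for excitatory neurons. The unfolded protein response call also ended without control replicate 2 (0.0548), trehalose 10 days replicate 1 (0.115) or 2 (0.0548), that of choroid plexus without replicate 2 (0.133), and that of excitatory neurons without replicate 1 (0.0605), 2 (0.0760) or 3 (0.324). Blank subtraction ended the calls of the unfolded protein response (adjusted p = 0.0505) and of excitatory neurons (0.102), and the latter also ended with 1 probe per gene (0.0928), array weights (0.0550) and the authors' table (0.0871). With the local background column no list was called at 10 days.

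**Figure D4:**
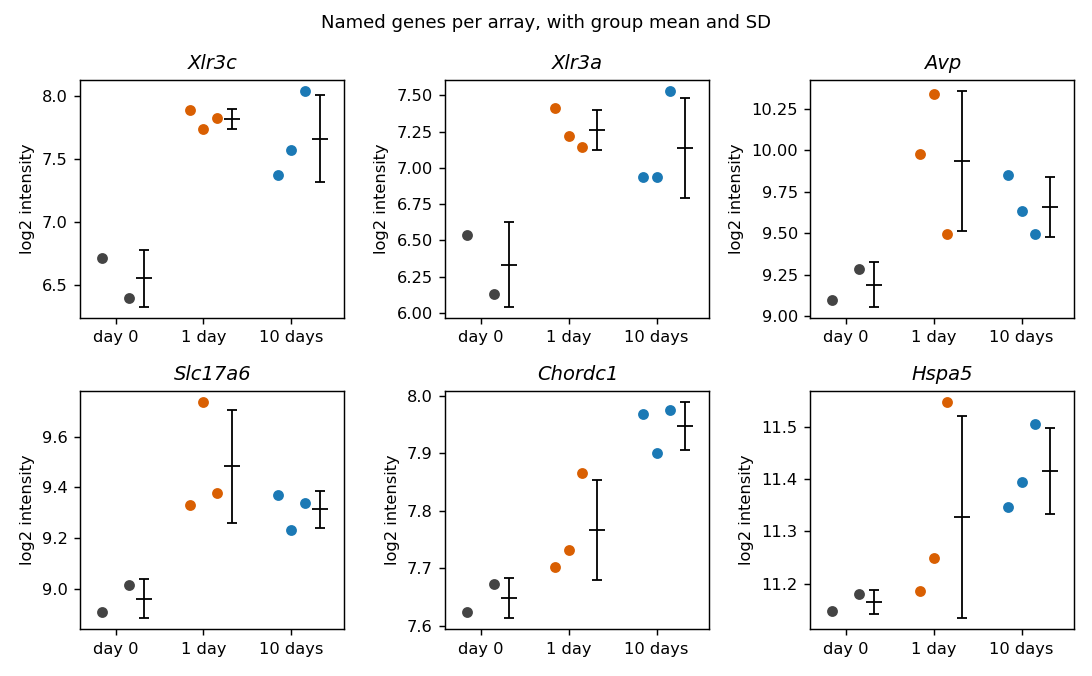
Log2 intensity of 6 named genes is shown per array (points) with the mean and SD of each group (bars): 2 control, 3 1-day and 3 10-day arrays. All trehalose arrays lie above both controls for each of the 6 genes, and none of the genes passed the test across all probes. Xlr3c, Xlr3a and Avp were named by a rule that required groups without overlap, and the others for a low p in their lists.

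The autophagy and lysosome lists were not called at 10 days either (adjusted p = 0.425 and 0.936). Nbr1 had a change of -0.13 (SE 0.05) and Psap, the precursor of lysosomal saposins, one of -0.31 (SE 0.11), which turned to 0.091 with the local background column. Treh had a change of -0.05 (95% interval -0.15 to 0.05) and Tfeb one of -0.04 (-0.17 to 0.09). Both probes were dim, so the offset compresses their changes and these intervals do not exclude a change. Pik3ca, the catalytic subunit of a kinase in insulin signalling, had a change of 0.26 (SE 0.05) and was the only one of the 27 probes in its list to pass when adjusted over the list alone, against 0 over all probes.

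The third comparison set 10 days against 1 day of trehalose and thereby tested whether the 2 times differed. Striatum markers were higher at 10 days than at 1 day by camera (adjusted p = 0.00685), with all 16 probes higher and a median of 0.22. The call was lost with an estimated correlation (adjusted p = 0.718). Drd1, a dopamine receptor gene named after its values were seen, had a change of 0.35 (SE 0.23). The glucocorticoid response list was not called (adjusted p = 0.0520), with 18 of 22 probes higher, and its adjusted p was 0.718 with an estimated correlation. Apart from the fit by replicate number, which the labels do not say pairs the mice, it was called under 6 of 16 other settings and not under 10, and the adjusted p of these 16 lay between 0.0205 (array weights) and 0.837 (fry). It was called in 5 of the 8 fits that left out 1 array. Without trehalose 1 day replicate 1 the adjusted p was 0.954, and without trehalose 10 days replicate 2 or 3 it was 0.202 or 0.439. Without trehalose 1 day replicate 2 or 3, or trehalose 10 days replicate 1, it was 0.00112, 0.00122 and 0.00309, and without control replicate 1 or 2 it was 0.0373 in each case. Klf9, a transcription factor induced by glucocorticoids, had a change of 0.19 (SE 0.05), and -0.0043 with the local background column. Chordc1 had a change of 0.18 (SE 0.05) and Crh, the hypothalamic releasing hormone of the stress axis, one of 0.18 (SE 0.06).

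Between the times limma called 0 of 21583 probes, with 756 at an unadjusted p under 0.05, 400 higher and 356 lower, against 1079 by chance. The 2 groups did not overlap for 8.39% of the probes, against 10% by chance for 3 against 3. With trend and robust variances the count was 1 gene, Il1rl2 (adjusted p = 0.00405), as it was after subtraction of the blank mean (adjusted p = 0.00364). Its probe may lie at background, as said for 10 days against control. Between the times fry called 0 lists, with a smallest adjusted p of 0.570. Without trehalose 1 day replicate 2 the direction of the striatum list turned (adjusted p = 0.686), and the call also ended without trehalose 10 days replicate 1 (0.0671) or 2 (0.0989) and with the local background column (0.280).

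The last comparison took trehalose at either time against control, 6 arrays against 2. Xlr3c had a log2 change of 1.19 (SE 0.16), Xlr3a one of 0.86 (SE 0.18) and Avp one of 0.61 (SE 0.20). Each was higher in all 6 trehalose arrays than in both controls, but the rule that named them required this, so it adds no support. Thalamus markers rose as a set (adjusted p = 1.24e-06, and adjusted p = 0.629 with an estimated correlation), with 17 of 19 probes higher, and Slc17a6 (0.44, SE 0.10) and Amotl1 (0.19, SE 0.05) passed when adjusted over the list alone. Choroid plexus and ependyma markers (adjusted p = 0.00391) and monoamine and brainstem markers (adjusted p = 0.0477) were higher, with Th, the dopamine-synthesis enzyme, at 0.29 (SE 0.18). Both calls were lost with an estimated correlation (adjusted p = 0.741 and adjusted p = 0.629). Excitatory neuron markers (adjusted p = 0.0143) and striatum markers (adjusted p = 0.0175) were lower. These calls were lost with an estimated correlation too (adjusted p = 0.629 and adjusted p = 0.788). None of these gene changes passed over all probes. With the local background column Slc17a6 stood at -0.25 and Amotl1 at -0.0080.

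At either time limma called 0 of 21583 probes, with 568 at an unadjusted p under 0.05, 360 higher and 208 lower, against 1079 by chance; 4.73% of the probes had separate groups, against 7.14% by chance. Against control replicate 2 alone, the log2 changes of Sult4a1 and Ifitm3 were 2.06 and 1.28. At either time fry called 0 lists, with a smallest adjusted p of 0.748. All 5 list calls ended without control replicate 1 (adjusted p = 0.194 for thalamus, 0.856 for choroid plexus, 0.476 for brainstem, 0.533 for excitatory neurons and 0.979 for striatum). Without trehalose 1 day replicate 2 the adjusted p of choroid plexus was 0.190, of brainstem 0.190 and of striatum 0.418. The brainstem call also ended without control replicate 2 (0.101), trehalose 1 day replicate 3 (0.0662) and trehalose 10 days replicate 3 (0.336), and that of striatum without the last of these (0.111). Array weights ended the calls of brainstem (adjusted p = 0.127) and striatum (0.110), and blank subtraction (0.0823) and no filter (0.0706) that of brainstem. With the local background column no list was called at either time.

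The changes at 1 and at 10 days correlated across probes with r = 0.569, and 66.7% had the same sign. Both comparisons use the same 2 controls. In 100 simulations of unchanged groups against shared controls, r averaged 0.601 (range 0.578 to 0.626) and 70.5% of the signs matched. The covariance was 0.00295, against 0.00346 in the simulations. The 2 controls were too few to give each comparison at least 2 control arrays of its own.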

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

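The tests of where a list's probes or medians lay on single arrays, the estimated correlation with an array left out, and the choice of replicate 2 at 1 day for these tests came after the results were seen. The striatum marker list differed between the 2 times of trehalose, with an adjusted p of 0.00685 by camera for 10 days against 1 day, a call that was lost with an estimated correlation (adjusted p = 0.718). All 16 of its probes had their lowest value of the 8 arrays in trehalose 1 day replicate 2. That array was picked as the lowest, so the 12.5% that chance gives for any array is no measure for it. In that array Penk, Rgs9, Ppp1r1b and Drd1, chosen after their values were seen, lay at -1.35, -1.29, -1.27 and -0.89 relative to the control mean on the log2 scale. In trehalose 1 day replicate 3 they lay at -0.54, -0.024, -0.57 and -0.25, and in trehalose 1 day replicate 1 at 0.38, 0.16, 0.011 and 0.13. A smaller share of striatum in the tissue of 1 mouse stays open: without trehalose 1 day replicate 2, picked as the lowest, the adjusted p at 1 day was 0.878, but without control replicate 1 it was 0.532 (leaving out each array gave 9.21e-12 to 0.878). A fall in every 1-day animal was not seen: by the list median 1 of the 3 arrays lay below both controls and by the list mean 2 did. The median of trehalose 1 day replicate 1 was 0.11, between those of the controls (0.15 and -0.15). With the medians of the controls 0.30 apart, a fall in that animal can be neither shown nor excluded.

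Thalamus markers were higher with trehalose at either time by camera, a call that was lost with an estimated correlation (adjusted p = 0.629) and without control replicate 1 (adjusted p = 0.194; leaving out each array gave 8.44e-09 to 0.194). Their median lay above both controls in 5 of 6 trehalose arrays. The camera call did not rest on trehalose 1 day replicate 2: without it the median change was 0.10 and the adjusted p 1.95e-05. With an estimated correlation the list was called neither with that sample (adjusted p = 0.629) nor without it (0.852), which cannot decide the question. A larger share of thalamus in that sample stays open for part of the rise. A larger share of thalamus tissue in several trehalose samples and an effect of trehalose on thalamic genes cannot be told apart, since both give probes that vary together (estimated correlation 0.377) and are higher with trehalose. The labels do not give the dissection of each sample.

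For 10 days against 1 day, the 6 trehalose arrays can be split into 2 groups of 3 in 10 ways, which is too few for a share under 0.05. The real split gave 756 probes at an unadjusted p under 0.05, and 9 of the 10 splits gave as many; the highest other count was 1882, from the split that sets samples 1, 2 and 4 against 5, 7 and 8 of the description numbers. The next was 1524, from samples 1, 7 and 8 against 2, 4 and 5, which does not follow the order of that number. Both exceed the 1079 that chance gives, as does the 1107 from samples 1, 2 and 8 against 4, 5 and 7. The remaining counts, the real one included, lay between 650 and 1042. A limma fit of the slope on the description number, with the groups included, was chosen after the results were seen. It gave 2343 of 21583 probes at an unadjusted p under 0.05, where chance alone gives about 1079. In it 0 probes passed the adjusted threshold, with a smallest adjusted p of 0.198. Whether this relation lies behind the counts of the splits was not tested. For probes past the adjusted threshold the real count was 0 and so was the highest other, so all 10 splits gave as many. For lists the real count was 1 and the highest other 9, and 9 splits gave as many.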

How the results depend on the processing

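The local background column, flagged spots kept, the sample number covariate, 1 probe per gene, and for lists also no background correction, cyclic loess, no filter, trend and robust variances, array weights and the compared groups alone were chosen after seeing the data. Of genes, 0 passed in every comparison under most settings. Subtracting the blank mean gave 1 at 10 days against control and 1 between the times, and so did trend and robust variances (1 and 1). The gene was Il1rl2 each time, whose probe may lie at background. Leaving out each array gave 0 to 2 genes at 1 day, 0 to 2 at 10 days, 0 to 0 between the times and 0 to 2 at either time; a lone control left by this was assumed to vary like the other groups. List counts were less stable. Leaving out each array gave 3 to 8 lists at 1 day, 0 to 5 at 10 days, 0 to 7 between the times and 0 to 7 at either time, against 5, 4, 1 and 5. An estimated correlation, fry and the local background column each gave 0 lists in all 4 comparisons. Lists at 1 day numbered 9 with array weights, 2 with blank subtraction and 8 with no background correction, and at 10 days 2 with blank subtraction. Between the times they numbered 2 with 1 probe per gene, 2 above the limit on all 8 arrays, 2 with array weights, 3 with the authors' table, 4 with median scaling, 2 with no background correction, 2 with the compared groups alone and 3 with the sample number covariate. At either time they numbered 3 with array weights, 9 with median scaling and 8 with the number covariate. The labels do not say that replicate numbers pair the mice. Deviations of same-numbered arrays from their group means correlated above 0.1 in 6 of 7 pairs (range -0.0247 to 0.263). These pairs are not independent, since the deviations within a group sum to 0. No pairing was taken because the labels give none, and a batch shared by same-numbered arrays stays open. As a hint from the data, 7 of 8 arrays followed an array of their own number best, and replicates 1, 2 and 3 hold the description numbers 1 to 3, 4 to 6, and 7 and 8. With the replicate block 0 genes were called, and the lists numbered 13 at 1 day, 5 between the times and 8 at either time, among them the glucocorticoid response (adjusted p = 4.41e-04, 5.38e-04 and 0.0407), while the calls of excitatory neurons at 10 days (0.0670) and brainstem at either time (0.0653) ended. Without trehalose 1 day replicate 2 the choroid plexus list at 1 day (adjusted p = 0.895; leaving out each array gave 7.40e-07 to 0.895) and the striatum list between the times (0.686; 5.53e-12 to 0.686) reversed. With the local background column the log2 changes of Amotl1 (-0.23 at 1 day, -0.0080 at either time), Slc17a6 (-0.58, -0.25), Scd2 (-0.42, -0.0014), Dnajb1 (-0.028 at 1 day), Nbr1 (0.12 at 1 day), Nrgn (0.18 at 10 days, 0.20 at either time), Psap (0.091 at 10 days) and Klf9 (-0.0043 between the times) reversed. Of 2851 values of named genes under alternatives, 12 reversed a change whose 95% interval excluded 0, and of the others 2590 moved by less than 1 SE and 249 further; 148 of all had the opposite sign. Of 370 values of called lists, 269 stayed past the threshold in their direction and 99 fell short of it. Where no reason is given, the cause was not tested. The median spot at 2.45 to 2.87 times the blank mean limits changes of dim probes. The comparison at either time has no value for the compared groups alone.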

Other observations

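Some genes induced by glucocorticoids differed between samples with low and high description numbers. Sgk1, a kinase, lay at -0.90 in sample 1 and 0.26 in sample 8 relative to the control mean on the log2 scale, Ddit4 at -0.39 and 0.15 and Tsc22d3 at -0.27 and 0.41. Per1, a clock gene that glucocorticoids also induce, lay at -0.24 and -0.04 in these samples and at its highest, 0.16, in sample 3. Hemoglobin transcripts varied widely: Hba-a2 ranged from -1.21 to 2.13 and Hbb-bs from -0.76 to 1.59, although the mice had been perfused. These genes were chosen after their values were seen. Oxt, which encodes oxytocin, lay at 0.86 in trehalose 1 day replicate 2, the array in which Avp was also highest at 1.15.

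The tests below, including those of relations with the sample number and of markers of other organs, were chosen after the results were seen. The mean of the glucocorticoid response list was higher at higher sample numbers, with Pearson's r = 0.831 (exact permutation p = 0.00809, adjusted over 42 lists 0.228) and Spearman's rho = 0.833 (exact permutation p = 0.0154, adjusted 0.220) over 8 samples; without samples 1 and 8, r was 0.686. The relation did not pass the correction over lists, and the list was taken up because its relation was the strongest of the 42. Its slope lay at percentile 100 of 10000 random lists of the same size and intensity. Probes of random lists were not chosen to vary together as those of this list do (estimated correlation 0.293), so a drift of all probes stays open: against the other probes, with the groups in the fit, the slope had a camera adjusted p = 4.03e-06, and an adjusted p = 0.638 with an estimated correlation. Differences between the groups alone can give an r of at most 0.189, and with the groups fitted the slope of the list mean was 0.032 per step of the number. That slope did not pass when the numbers were permuted within groups (exact permutation p = 0.0833, two-sided, where the smallest possible is 0.0278), so a rise within groups was not established. What the number stands for, such as an order of handling, is not given in the labels and was not tested.

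Transcripts of liver were seen in brain RNA. Mup2, Mup19 and Alb lay at 1.10, 1.05 and 0.92 in control replicate 1 and at -1.39, -1.19 and -1.10 in trehalose 1 day replicate 1, on the log2 scale relative to the control mean. In control replicate 2 they lay at -1.10, -1.05 and -0.92. They lay at 0.39, 0.26 and -0.015 in trehalose 1 day replicate 3, and at 0.32, 0.44 and 0.0038 in trehalose 10 days replicate 2. The values therefore did not follow the groups. The 7 probes seen first shared a mean correlation of 0.974, but they were picked because they varied, and among the 41 other liver probes it was 0.376. Failed spots on single arrays are argued against by those other probes, whose mean followed that of the 7 over the 8 arrays with Pearson's r = 0.958 (exact permutation p = 0.00179) and Spearman's rho = 0.762 (exact permutation p = 0.0368). Without control replicate 1 and trehalose 10 days replicate 2, r was 0.942. RNA from liver in some samples may be the source. The spread between arrays of the 41 other liver probes lay at percentile 100 of random lists, while kidney, skeletal muscle and pancreas markers lay at 91.1, 23.1 and 74.4. Probes of random lists were not chosen to vary together as these liver probes do, which alone can raise the spread of their mean. The probes of kidney, skeletal muscle and pancreas varied together less (mean correlation 0.155, -0.053 and 0.093), so the percentiles cannot decide on the source. Of these 41 probes, for 39 genes, 33 were above the limit on all 8 arrays and 1 gene belonged to the lists above, so brain tissue itself may express part of them, and no biological explanation was tested.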
